A study of Homo sapiens with 2 samples.

How the data were processed

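Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with an antibody against CREB, a cAMP- and calcium-responsive transcription factor, in NGP, an established human neuroblastoma cell line. Per the labels' protocols, cells were grown in medium with 20% serum and harvested at 80 to 90% confluency. The immunoprecipitation used a commercial kit, libraries were made from 4 ng of DNA, and amplified fragments of 250 to 450 bp were selected. The series holds 1 CREB ChIP library and 1 input library (DNA taken without immunoprecipitation), with no replicate of either, so no value below has an error between cultures.

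The processed data were a peak list and a table of peaks near transcription start sites (TSS), both of the ChIP library. Per the submitters' processing notes, Bowtie2 and MACS2 were used with genome build hg38. Versions, settings, read filters and the treatment of duplicate or multiply aligned reads are not given in the sources used here. In the peak list deposited by the authors, each peak carries a fold enrichment (a ratio), a −log10 p-value and a −log10 q-value at its summit, as the narrowPeak format defines them, and a score. The deposited score equalled the whole part of 10 times the −log10 q in all 5285 peaks. The lowest −log10 q was 1.32, which is a q of about 0.05. The table deposited by the authors pairs peaks with refGene TSS. All 4780 of its rows matched the peak list in position and score, the largest gap from peak to TSS was 49999 bp, and each of its 2495 symbols had 1 TSS. All fold and q values below are the authors' own and are used only to describe, rank or filter peaks within this list.

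No genome sequence was used here. RefSeq gene positions of GRCh38.p14, the same build, gave 19974 protein-coding genes on chromosomes 1 to 22 and X, with gene start and end but no strand. Of the table's symbols, 2384 were found there directly and 1692 were matched to a protein-coding gene by current or older symbol. The TSS and strand were taken from the authors' table, which lay within 100 bp of the RefSeq gene end for 85.6% of the protein-coding genes. The table left out 94 of the 1223 protein-coding genes that had both ends within 49 kb of a peak, and 58 of these had a LOC symbol.

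The planned tests of the cAMP response element and of 8-mers at summits need the genome sequence and were not run. A promoter peak was a peak with its summit within 1 kb of the TSS of a protein-coding gene. The share of peaks near genes was compared with 1000 random placements of the peaks, one-sided. Because RefSeq gave no strand, that test counted summits within 1 kb of either end of a protein-coding gene, and random positions were drawn between the outermost genes of the same chromosome without removing assembly gaps. This departs from the plan, which excluded gaps and used TSS alone. Gene lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over 27 lists. The lists held 720 entries (701 distinct genes), of which 719 were matched. Fold enrichments were compared with permutation tests of 100000 resamples. All p-values run over peaks or genes of this 1 ChIP library and describe this peak list, not the condition.

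The number of fragments behind each peak was recovered from its fold and p. Taking fold as (pileup + 1) / (background + 1) and p as a Poisson tail, a whole number of fragments gave the −log10 p within 0.001 (above a −log10 p of 100, within a relative 1e-05) in 5285 of 5285 peaks. The relative tolerance was added after the EEF1A1 peak was not recovered without it, since its values are rounded to 6 digits. With p-values shuffled among the peaks this held for 3.18%. The recovered background is the number of fragments the peak caller expected at the summit. Intervals on fragments are exact Poisson intervals at 95%, intervals on shares are exact Clopper-Pearson intervals at 95%, and both cover counting error only, since the reads carry no molecular identifiers.

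The rule for named genes, the gene lists and most of the other settings tried were set before the data were examined. The rule took the 15 protein-coding genes with the highest fold among promoter peaks (1 gene per peak, the nearest TSS), up to 3 members per list with the highest fold, and CAMKV, CREB1, MYCN, FOS, NR4A1 and CREM whatever their values. Other strong peaks, list members with a peak beyond 1 kb of the TSS, MRPL55, RFC3, CDC27 and genes in the closing section fall outside this rule and were chosen after their values were seen. The division of the genome into 1 Mb windows with 10 or more peaks and the rest, the fragment recovery, the comparison of gene starts with gene ends, the comparison of fold at promoters and the vector and copy-number checks were also chosen after the data were seen. Alternatives were a stricter q, the upper part of the peaks by fold, distances of 500 bp and 5 kb, other gene sets and other peak sets. On simulated data, the recovery returned the right pileup and background in 100.0% of 1985 peaks. The list test, run on 40-gene lists among 19974 genes, passed p of 0.05 in 2.5% of lists without an effect. It called 35.5%, 94.0% and 100.0% of lists whose share with a promoter peak was 10%, 20% and 30%, at a Bonferroni threshold over 27 lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.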

Results

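Regions enriched by CREB ChIP were mapped in NGP neuroblastoma cells. Per the series' design text, the purpose was to find genes that lie downstream of CAMKV, a pseudokinase of the calcium/calmodulin kinase family, through CREB. The data comprised 1 CREB ChIP library and 1 input library, and the values below are those of the ChIP library's peaks. The deposited list held 5285 peaks with a median width of 236 bp (quartiles 185 to 332 bp). Their median fold enrichment was 5.24 (quartiles 4.46 to 6.42), and 216 peaks reached a fold of 10. Most peaks rested on few fragments. The median summit held 6 fragments (quartiles 5 to 9), 79.1% of peaks held at most 9, and the fewest was 4, against a median expected background of 0.316 fragments.

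The first question was where in the genome CREB peaks lay. Most of the list lay in a small part of the genome: 3130 peaks (59.2%, 95% interval 57.9 to 60.6) fell in 62 windows of 1 Mb that held 10 or more peaks each. On chromosome 6, 480 of 595 peaks lay between 58 and 60 Mb, and on chromosome 20, 543 of 589 peaks lay between 26 and 29 Mb. Both intervals flank or contain the centromere, as do 40 to 42 Mb on chromosome 10, with 217 peaks, and 58 to 61 Mb on chromosome 7, with 209 peaks. A further 347 peaks (6.57%, 95% interval 5.91 to 7.27) lay outside chromosomes 1 to 22 and X, on unplaced, alternative, mitochondrial or other sequences. The remaining 1808 peaks (34.2%, 95% interval 32.9 to 35.5) were spread over the other windows. Peaks of the dense windows had a median fold of 5.51 and those of the other windows 4.80.

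**Figure D1:**
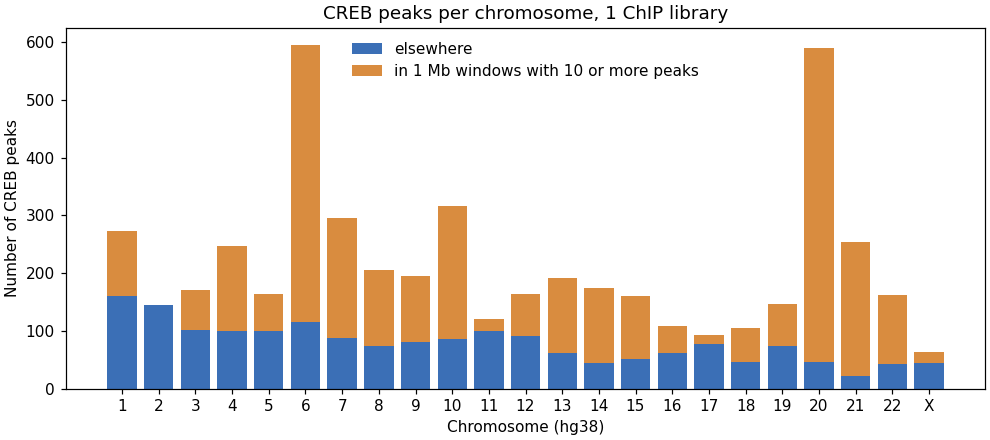
Bars give the number of CREB peaks on chromosomes 1 to 22 and X (x axis), split into peaks in 1 Mb windows with 10 or more peaks (orange) and peaks elsewhere (blue). Chromosomes 6 and 20 carry 595 and 589 peaks, most of them in such windows.

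Gene families and single genes with several peaks were among the sites. The 45S rRNA units, which encode the large ribosomal RNAs, overlapped 30 peaks, at 3 of 4 annotated units, with a median fold of 9.12 and a maximum of 21.7. The USP17L genes, a tandem family of deubiquitinases on chromosome 4, overlapped 18 peaks at 15 of 29 genes, with a median fold of 6.08. NBPF genes overlapped 17 peaks and REXO1L genes 6. The lncRNA genes DANT1 and DANT2 on the X chromosome overlapped the same 13 peaks, and the single genes TTC34 and LPA overlapped 8 and 6. Of 521 annotated 5S rRNA genes and pseudogenes, 4 overlapped a peak. The rRNA units and the members of the USP17L, NBPF and REXO1L families share near-identical sequence, so the assignment of their reads to a single copy is uncertain. Whether the peaks in DANT1, DANT2, TTC34 and LPA lie in repeated sequence was not examined, so they are not shown to be separate sites.

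The strongest peaks stood far above the rest of the list. The peak at the start of EEF1A1, which encodes translation elongation factor 1 alpha, had a fold of 634 with 833 fragments (95% interval 777 to 892) over a background of 0.316. It spanned positions 73520976 to 73521255 of chromosome 6. The next were a peak covering IGKC, the immunoglobulin kappa constant region, on chromosome 2 (fold 226, 296 fragments) and a peak at RNU6-1, a U6 small nuclear RNA gene, on chromosome 15 (fold 159, 208 fragments). A peak within CAMK1D on chromosome 10 had a fold of 132. CAMKV itself carried 3 peaks, on chromosome 3. Peaks at 49860462 to 49861585 and 49862037 to 49862390 had folds of 90.7 and 79.0, with 112 (95% interval 92.2 to 135) and 103 (84.1 to 125) fragments, and ranked 6 and 7 in the list. The other, at 49859354 to 49859565, had a fold of 5.62 with 6 fragments. All 3 lay 7.8 to 10.4 kb downstream of the CAMKV TSS at 49869906, within the gene, and none lay within 1 kb of it. A peak at HBB, the beta-globin gene, had a fold of 56.2 and a peak within RNF26, which encodes a ring-finger protein, a fold of 30.4. Peaks at 10011 to 11783 of chromosome 5 (fold 94.8) and 133264939 to 133265304 of chromosome 12 (fold 62.1) overlapped no annotated gene. Both lay near an end of their chromosome, as did peaks on chromosomes 10 (fold 50.3), X (43.8), 18 (37.5), 1 (26.3) and 22 (23.1). Backgrounds at these peaks were 0.632 to 1.9 fragments, against 0.316 at EEF1A1. Whether they mark single sites was not tested. No peak lay within 1 kb of the related genes RNU6-2, RNU6-7, RNU6-8, RNU6-9, RN7SK, RMRP, EEF1A2 or PGK2.

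**Figure D2:**
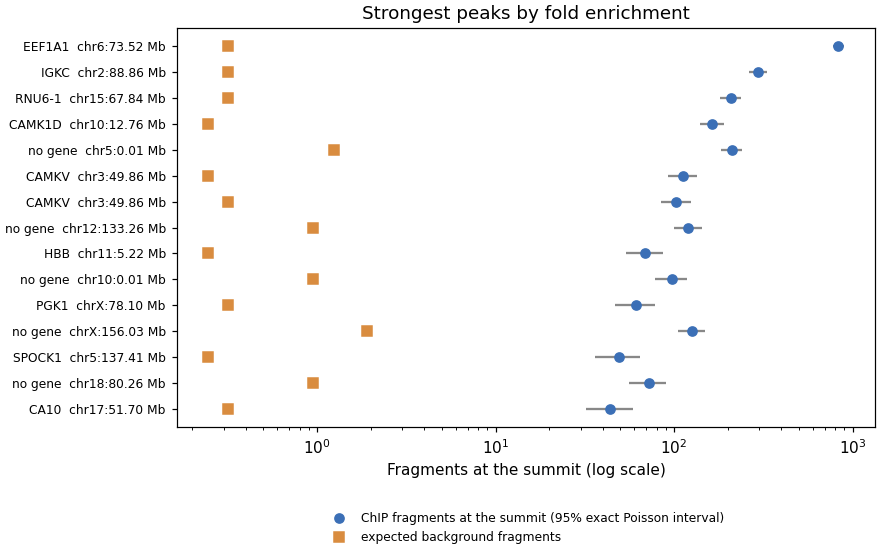
Blue points give the ChIP fragments at the summit with 95% exact Poisson intervals, and orange squares the expected background fragments, on a log scale, for the peaks on chromosomes 1 to 22 and X among the 16 with the highest fold. EEF1A1 stands at 833 fragments against a background of 0.316, and the CAMKV peaks at 112 and 103.

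**Figure D3:**
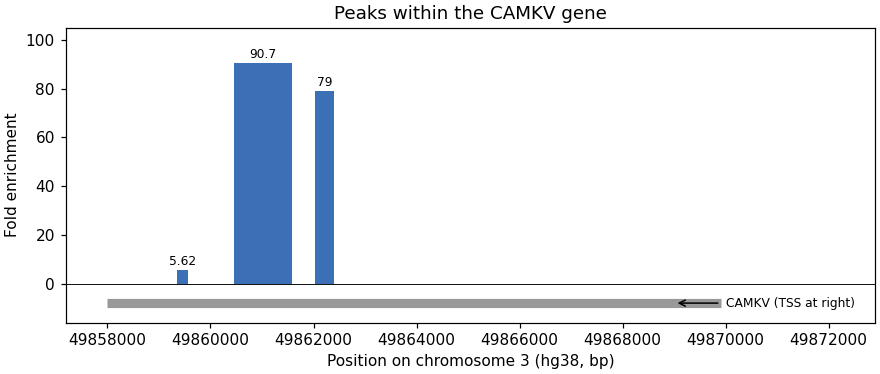
Bars mark the 3 peaks along the CAMKV gene (grey line; x axis, hg38 position on chromosome 3) with fold enrichment as height and peak width to scale. The folds from left to right are 5.62, 90.7 and 79.0, and the TSS side of the gene holds no peak.

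A small part of the list lay at promoters. Of 4938 peaks on chromosomes 1 to 22 and X, 222 (4.50%, 95% interval 3.94 to 5.11) had the summit within 1 kb of a protein-coding TSS, and these marked 265 genes, 1.33% of the 19974 protein-coding genes. Outside the dense windows the share was 11.8% (213 peaks, 95% interval 10.3 to 13.4), and within them 0.288% (9 peaks). Counting either gene end, 5.41% of peaks lay within 1 kb, against a median of 2.51% and a maximum of 3.18% over 1000 random placements (permutation test, one-sided, p = 0.001, the smallest these placements can give). Within 5 kb the order turned, with 9.38% of peaks against a random median of 10.6%.

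Summits clustered at the start of genes. The median distance from a promoter summit to the nearest TSS was 103 bp, 164 of 222 summits (73.9%) lay within 200 bp, and 132 lay upstream and 89 downstream. Among 1048 protein-coding genes of 3 to 45 kb in the authors' table, 160 had a peak within 1 kb of the TSS end alone and 20 of the other end alone (exact binomial test, two-sided, p = 2.6e-28). Outside the dense windows, promoter peaks had a median fold of 5.60 and the other peaks 4.59. The difference of mean log2 fold was 0.29 ± 0.05 (SE; 213 against 1595 peaks; permutation test, two-sided, p = 1e-05, the smallest the resamples can give). Without the EEF1A1, PGK1 and PARP2 peaks it was 0.23, and over all peaks of chromosomes 1 to 22 and X, where the medians were 5.61 and 5.17, it was 0.18. Of the promoter peaks, 39 lay within 1 kb of the TSS of 2 or more protein-coding genes, so that the peak cannot be assigned to 1 of them.

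**Figure D4:**
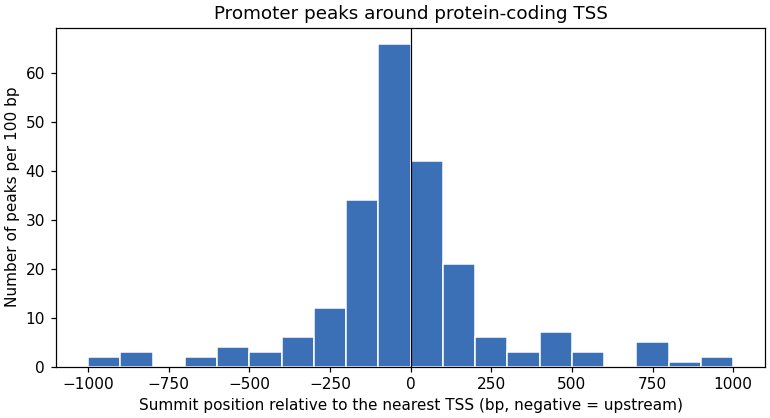
The histogram counts promoter peaks per 100 bp (y axis) by the position of the summit relative to the nearest protein-coding TSS (x axis, bp, negative upstream). The 222 summits pile up close to the TSS, 164 of them within 200 bp.

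The 15 genes with the highest promoter fold had folds from 10.3 to 634. After EEF1A1 came PGK1, which encodes the glycolytic enzyme phosphoglycerate kinase, with a fold of 47.1 and 61 fragments (95% interval 46.7 to 78.4), its summit 156 bp upstream of the TSS on the X chromosome. PARP2, a DNA repair enzyme, had a fold of 23.5 with 29 fragments (19.4 to 41.6). Its peak lies between PARP2 and RPPH1, the RNA component of RNase P, which is transcribed from the same short interval. The promoters of EEF1A1, PGK1 and RPPH1 are commonly built into vectors. Construct DNA is therefore a candidate explanation for these peaks, taken up in the closing section. VPS37B, a subunit of the ESCRT-I sorting complex, had a fold of 18.4 with 64 fragments over a background of 2.53. SNX16, a sorting nexin, had a fold of 17.7. VMP1, an autophagy membrane protein, had a fold of 15.2, at a start shared with PTRH2. FBXW7, the substrate receptor of a ubiquitin ligase for cyclin E and MYC proteins, had a fold of 13.6 with 16 fragments. TSPAN31, the neighbour of CDK4, had a fold of 13.1 and METTL1, a tRNA methyltransferase, a fold of 10.3, over backgrounds of 2.37 and 2.97. The others were TMEM80 (fold 12.6), ZFPL1 (12.2, at a start shared with CDCA5), PGAP2 (12.1, with NUP98 on the same peak), PEF1 (12), STAMBP, a deubiquitinase of the endosome (12), and TPP2, a peptidase (10.4).

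Known CREB-responsive genes were then examined as a list. Of 43 such genes, 3 had a promoter peak (6.98%), against 1.31% of the other protein-coding genes (odds ratio 5.63, Fisher's exact test p = 0.019, Benjamini-Hochberg adjusted p over the 27 lists = 0.29). The 3 were immediate-early transcription factor genes. FOS had a fold of 6.69 with 8 fragments (95% interval 3.45 to 15.8), its summit at position 75278736 of chromosome 14, 92 bp upstream of the TSS. EGR1 and FOSB each had a fold of 4.82 with 5 fragments (1.62 to 11.7), 269 and 179 bp upstream. Of these only FOS passed a −log10 q of 5, and with that threshold the list held 1 gene and an adjusted p of 0.64 in Fisher's exact test. Over all settings tried the adjusted p of this list ranged from 0.22 to 0.93. Within 50 kb the list held 7 of the 43 genes. The other 4 were PER1, a clock gene, with a peak 2.0 kb upstream (fold 4.68), STAR, a steroidogenic gene, 6.3 kb upstream (4.63), BDNF, a neurotrophin gene, 24.3 kb upstream (4.46) and CCND1, the cyclin D1 gene, 27.7 kb downstream (4.72). NR4A1, CREM and CREB1 had no peak paired with them within 50 kb in the authors' table. That table gives 1 TSS per symbol, so any other starts of these genes were not examined. None of the 13 CREB-family and coactivator genes had a promoter peak.

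Genes of the neuroblastoma state were examined next, in lists too short to tell a count of 0 from the 1.33% of all genes (Fisher's exact test, p = 1 for each list without a promoter peak). None of the 21 adrenergic core regulatory genes, MYCN among them, had a peak within 50 kb of the TSS, and none of the 25 mesenchymal-state genes had a promoter peak. VIM, an intermediate filament gene of that list, had a peak 1.2 kb downstream of its TSS with a fold of 14.4. Of 26 neuroblastoma oncogenes and risk genes none had a promoter peak, and 3 had one within 50 kb, namely CDK4, CCND1 and ARID1B. The peak paired with CDK4 is the one at the TSPAN31 start. Among 14 catecholamine and chromaffin genes, MAOA, a monoamine-degrading enzyme, had a promoter peak with a fold of 4.90 and 7 fragments. No promoter peak was found at the members of the lists of 40 cell-cycle and replication, 20 clock, 25 apoptosis, 25 autophagy and lysosome, 34 mitochondrial ribosome and 30 synaptic and neuronal genes. These lists are not complete, so a count of 0 in a list does not describe all genes of its kind. MRPL55, a mitochondrial ribosome gene outside them, had a promoter peak with a fold of 9.63, in a dense window of chromosome 1. Promoter peaks outside the lists also lay at VMP1 of autophagy (fold 15.2), RFC3 of DNA replication (5.62) and CDC27 of the cell cycle (7.51).

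Of 22 calcium/calmodulin signalling genes, CAMK2N2, an inhibitor of CaM kinase II, had a promoter peak (fold 4.01, 4 fragments). Within 50 kb the same list also held CAMK1, at 6.9 kb with a fold of 11.9, CAMK2G, CAMK1G, PPP3CA and CAMKV. Of 27 cAMP and PKA signalling genes, PDE7A, a cAMP phosphodiesterase, had a promoter peak with a fold of 6.42. The respiratory chain list held 3 of 45 genes (Fisher's exact test p = 0.022, adjusted p = 0.29): NDUFA10 of complex I with a fold of 7.71, NDUFB5 of complex I with 4.81 and COX7C of cytochrome c oxidase with 4.01. The proteasome list held PSMD3 (7.27) and PSMB2 (4.82) among 32 genes. The translation factor list held EEF1A1 and EIF2B1 (5.30) among 39. RPL9 (6.42), SRSF11 (8.36), DNAJB11 (7.22) and PARP2 were the single members marked in the cytosolic ribosome, splicing, endoplasmic reticulum chaperone and DNA repair lists. Several of these peaks are shared with another gene: RPL9 with LIAS, SRSF11 with LRRC40, DNAJB11 with TBCCD1, EIF2B1 with GTF2H3 and NDUFB5 with MRPL47. The summit lay nearer to the TSS of LIAS, TBCCD1 and GTF2H3 than to that of the list member. For the EEF1A1 and PARP2 peaks, construct DNA is a candidate explanation, as said above. Of 99 entries over 6 lists of markers of other cell types (glia, fibroblasts, leukocytes, hepatocytes, skeletal muscle and keratinocytes), none had a promoter peak (pooled Fisher's exact test, p = 0.64).

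No list passed Benjamini-Hochberg adjustment over the 27 lists in Fisher's exact test, and 2 passed an unadjusted p of 0.05. In simulated 40-gene lists at a Bonferroni threshold, a share of 10% was called in 35.5% of lists and a share of 20% in 94.0%. A share of 10% or less would thus mostly be missed in lists of that length. Most of the lists tested here were shorter, and their power was not simulated.

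The authors' deposited table, which links peaks to possible target genes, named 2495 symbols, paired with 1314 of the 5285 peaks. Of these symbols, 370 had a summit within 1 kb of the TSS, 582 within 5 kb and 2487 within 50 kb, and the median distance over all pairs was 21075 bp. Protein-coding genes numbered 1692, which is 8.47% of all. Dense windows gave 2144 of the 4780 pairs (44.9%), and 113 symbols were paired with peaks of dense windows alone. Chromosome 21 alone gave 1254 pairs, and MIR10396A, a microRNA gene, was paired with 64 peaks.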

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

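All tests in this part were chosen after the values they concern had been seen.

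The peak within CAMKV, with a fold of 90.7, lies in gene-body sequence that the promoter comparisons leave out, and the starts of EEF1A1 (fold 634), RNU6-1 (159), PGK1 (47.1) and RPPH1 (23.5) are also among the 21 strongest peaks. The promoters of these genes are commonly built into expression and shRNA vectors. Among 83 other ribosome and translation factor genes 2 had a promoter peak, the higher with a fold of 6.42. Folds like that of EEF1A1 were thus not general at the promoters of such genes. That comparison does not cover PGK1, RNU6-1, RPPH1 or the CAMKV gene body, where strong promoter use stays open. The background at these 5 loci was at most 0.316 fragments, close to the commonest background of the list, 0.246. A high fold already requires a background that is low beside the pileup. The low background therefore follows from the choice of loci and cannot decide whether construct copies lay in both libraries. Construct DNA with CAMKV sequence in the ChIP library but not in the input is a candidate explanation. Of 8 related genes (RNU6-2, RNU6-7, RNU6-8, RNU6-9, RN7SK, RMRP, EEF1A2 and PGK2), 0 had a peak. Since only 1.33% of protein-coding genes had a promoter peak, a count of 0 was likely with or without a construct and decides nothing. The labels name no construct, while the peak names in the deposited list carry CAMKV beside CREB. A construct that itself binds CREB was not tested and stays open. The strong peaks at IGKC, CAMK1D, HBB and near chromosome ends also stay open, as they were not among the loci tested. CREB binding in the cells at all of these loci likewise stays open.

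Peaks outside chromosomes 1 to 22 and X numbered 347, with a median of 19 fragments over a background of 1.65, and no explanation was tested for them. In the dense window of chromosome 21 that holds the rRNA units, the median background was 13.7 times that of peaks elsewhere, so reads of many copies stacked on few annotated ones may account for part of the peaks there. The peaks on the 45S units had a lower median background, 0.819 fragments, and the strongest of them in that window, with folds of 21.7 and 20.4, had 0.658 and 0.272, the latter below the median of 0.287 elsewhere. In the other dense windows the median background was 1.1 times that of peaks elsewhere. Background was known only at called peaks, where the ChIP library exceeds it. The ratio therefore cannot decide whether copies raise both libraries alike in these windows. Of all 62 dense windows, the rRNA window of chromosome 21 included, 14 had a median background at least 2 times that of peaks elsewhere. In the dense windows other than that one, 57.7% of the peaks lay at or below 0.316 fragments, against 77.5% elsewhere. Reads spread at random over near-identical repeats, CREB binding to satellite DNA and chance stacks of few fragments were not tested and stay open.

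The median background of the 5 peaks within 1 Mb of CDK4 or MDM2 was 2.21 fragments, 7.7 times that of peaks elsewhere. Of the 6 promoter peaks outside dense windows with a background over 1.5, 5 lay on chromosome 12, at TSPAN31, METTL1, CPSF6, CCT2 and VPS37B. Extra copies of CDK4 and MDM2 in NGP, a line described as carrying them amplified, may raise it, but the loci were picked after the value of 2.21 was seen, so no test here decides. The peak at R3HDM2, also within 1 Mb of CDK4, had a background of 0.386, and VPS37B, with 2.53, lies at 122.9 Mb, far from both genes. VPS37B was not an isolated case there. A peak 1.4 kb from the DIABLO TSS, at 122225783 to 122226234 of chromosome 12, held 35 fragments at a fold of 8.65. Those values also imply a background over 1.5, and the cause at either site was not tested. A local difference in alignment was not tested, no biological explanation other than extra copies was examined, and no peak lay within 1 Mb of MYCN.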

How the results depend on the processing

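With −log10 q of at least 5, the 5285 peaks became 1601 and the 265 protein-coding genes with a promoter peak became 106. The upper 2640 peaks by fold gave 163 genes. Outside dense windows and other sequences 1808 peaks remained. The promoter share of 4.50% was 6.89% at 5 kb, 0.288% in dense windows and 11.8% outside them. The test counted both gene ends: these shares were 4.44 to 9.50% over the planned settings within 1 kb, each above its random placements, but 9.38% against a random median of 10.6% at 5 kb (permutation test, p = 0.999) and 1.09% against 2.43% in dense windows (permutation test, p = 1.0). The cause was not tested. The number of gene lists past adjustment was 0 in all 7 settings, and the lowest adjusted p ranged from 0.22 to 0.93. In all, 26 of 32 alternative values were judged the same as their main value, and 20 of the 32 were planned. For tests this meant the same direction and side of the threshold. Counts have neither and were judged by size. For example, the 391 genes with a promoter peak at 5 kb were judged the same as 265, and 163 were not. The settings on dense windows, the gene-end comparison, the fold comparison and the background without LOC symbols were added after the data were seen. The 4 planned results on sequence motifs and their alternatives were not run, nor were the alternatives on CpG-rich promoters and matched random lists, since no genome sequence was used here. No paired analysis was possible because the series has 1 library per group; leaving out a replicate was not possible for the same reason. The median of 6 fragments per summit limits the precision of most folds.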

Other observations

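Below the 15 genes named by fold, further promoter peaks lay at genes that belong to none of the lists. A selection of them is given here as values. It was made after the values were seen, and no theme among them was tested. HNRNPA3, which encodes an RNA-binding protein, had a fold of 9.88, TBL3 9.62 and SMU1, a splicing factor gene, 9.07. RAB8A, a GTPase of vesicle transport, had a fold of 8.60 and TOP2B, a DNA topoisomerase, 8.45. VPS4B and TSG101, both of the ESCRT sorting machinery, had folds of 7.83 and 7.71, and PPM1D, a phosphatase gene, had 7.43.

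The recovered backgrounds may hold values of both libraries. The commonest was 0.246 fragments, in 1657 peaks, and the next was 0.316, with further groups at 2, 3 and 4 times 0.316 (364, 165 and 79 peaks). If 1 input fragment is worth 0.316 ChIP fragments, the input held 3.16 fragments per ChIP fragment. This assumption was not tested.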
